A study of Mus musculus with 5 samples.

How the data were processed

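RNA sequencing of sorted mouse pancreatic cancer cells was analysed in 5 libraries. Per the labels, the cells derive from the HY15549 line, with a C57BL/6 strain background, and carry a GFP-LC3-RFP reporter of autophagy flux. They were grown as organoids in Matrigel, a basement membrane gel, dissociated to single cells and sorted on the ratio of GFP to RFP signal into an autophagy-high population (AThi, 2 libraries) and an autophagy-low population (ATlo, 3 libraries). Total RNA was column-purified and libraries were made with a stranded mRNA kit, per the labels' protocols. The series describes its samples as biological replicates, and no label used here says whether they came from separate cultures, so the p-values measure the spread between these libraries.

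The values are FPKM (fragments per kilobase of transcript, scaled to the depth of the library), deposited by the authors in 1 table with a column per library and rounded to 2 decimals. The name of the table speaks of counts as well, and no column of whole-number counts was used here. The submitters' processing notes name bcl2fastq, STAR, featureCounts and DESeq2 and the builds mm10 and GRCm38, without versions. The annotation release, the treatment of reads that map to several places, the strand setting and the formula of the FPKM are not given in the sources used here. FPKM are relative values within a library, so a change in the amount of RNA per cell leaves no trace in them. Genes with near-identical copies elsewhere in the genome, such as many ribosomal protein genes, Gapdh, the Hspa1a and Hspa1b pair, the class I histocompatibility genes and several mitochondrially encoded genes, can lose or share reads in such counting, and their values are uncertain. The table held 52459 rows, of which 28341 were 0 in all 5 libraries. In 26 rows a date-like number stood in place of the symbol. These rows were kept in the tests and not named.

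The depth was read from the low values. In single-exon genes of up to 200 nucleotides, FPKM times length fell on whole multiples of 1 step per library (tolerance 0.1 of a step, 285 to 394 values per library, 100% whole). The step gave an implied depth of 27.6 and 44.9 M reads (M, 1e6) for AThi replicates 1 and 2, and of 42.1, 36.0 and 39.2 M for ATlo replicates 1 to 3. For a transcript of 1 kilobase, 3 reads correspond to between 0.067 and 0.109 FPKM in these libraries. This floor covers counting error only. Coordinates and exon lengths came from the GENCODE M21 annotation of GRCm38, the assembly the processing notes name, and 47982 symbols of the table matched 1 annotated gene. Coordinates are 1-based.

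The test was chosen before the data were examined, in one form for counts and another for FPKM, and the FPKM form was used. Genes with a mean of at least 1 FPKM over the 5 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend) on log2(FPKM + 0.5), two-sided, with group as the single term. The threshold was a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes below come from this limma fit. Fold changes are on the log2(FPKM + 0.5) scale, AThi minus ATlo, which understates the change of genes with low values. The fit had 3 residual degrees of freedom and a prior of 3.89. It was tested on simulated data for 11397 genes with 200 changed: 79.1% of the 1.5-fold, 97.0% of the 2-fold and 98.5% of the 4-fold changes of this comparison were recovered, and 12 unchanged genes passed. The simulated noise was independent between genes, and in the real data 5884 genes passed. These rates therefore leave out correlation between genes and effects shared by a library.

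In all, 35 gene lists were fixed before the data were examined, and the 30 with at least 5 tested members were tested with limma's camera, which asks whether a list's genes moved differently from the other tested genes. The correlation between genes was preset to 0.01, and Benjamini-Hochberg adjustment ran over the 30 lists. Camera with an estimated correlation and fry were run beside it. The tested lists covered autophagy machinery, autophagy receptors, lysosome, MiT/TFE and mTORC1, ATF4, unfolded protein response, glycolysis, hypoxia, oxidative phosphorylation, cholesterol, fatty acids, NRF2, S phase, G2/M, class I presentation, interferon, NF-kB, MAPK, p53, epithelial, mesenchymal, pancreatic, basal-like, stem cell-associated, proteasome, ribosomal protein, mitochondrially encoded, immediate-early, iron and growth factor genes. The other 5 lists held markers of immune, fibroblast, endothelial, acinar, and endocrine or erythroid cells and are given as levels. Per-library shares of the summed FPKM were compared with an exact two-sided permutation test in SciPy 1.17.1. With 2 libraries against 3 its smallest p is 0.2, so it cannot reach 0.05.

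The genes named were set by a rule fixed before the data were examined. It took the 15 largest changes in each direction among genes past the threshold with a mean of at least 2 FPKM and no overlap of the library values of both groups, leaving unnamed any symbols of predicted or numbered transcripts. It added the 4 members of each list with the smallest p, every member past the threshold of the autophagy machinery, autophagy receptor and lysosome lists, and Map1lc3b, Sqstm1, Tfeb, Tfe3 and Mitf. The lists that did not pass are described with fewer genes, and some genes that the rule took are not reported here. Some members of the fixed lists that were below the filter are also named, as levels. Any other gene is named as chosen after its values were seen.

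Alternatives fixed before the data were examined were the replicate number as a block, each library left out, pseudocounts of 0.1 and 1, no filter on low values, a minimum mean of 5 FPKM, rescaling to TPM, median-ratio scaling, quantile normalization, eBayes without trend and with robust moderation, library weights, the mitochondrial and 20 most abundant genes left out before rescaling, a fold of 2 as a second threshold, and an adjusted p under 0.1. After the data were seen, limma's voom on reads estimated from FPKM, exon length and implied depth was added.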

Results

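Messenger RNA was profiled in mouse pancreatic cancer cells sorted from organoids by an autophagy reporter. Autophagy delivers cytoplasmic material to the lysosome for degradation, and the GFP-LC3-RFP reporter reads its flux as a ratio of green to red fluorescence. There were 2 libraries of AThi (autophagy-high) and 3 libraries of ATlo (autophagy-low) cells. Between 19151 and 20412 genes had a value above 0 in a library, at implied depths of 27.6 to 44.9 M reads. On log2 values, Pearson's r across genes was 0.990 to 0.992 between libraries of a group and 0.926 to 0.948 between libraries of different groups, where genes are not independent replicates. The first principal component separated the groups and held 84.2% of the variance.

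The comparison of AThi with ATlo addressed which genes differ between cells of one tumour line with high and low autophagy flux. AThi cells had far lower transcript levels of cell division genes, led by Ccna2, the cyclin A2 gene, at 2.70 ± 0.52 FPKM in AThi (SD, n = 2) against 45.4 ± 7.46 FPKM in ATlo (SD, n = 3). All 31 proteasome genes, all 24 cholesterol synthesis genes and 24 of 38 nuclear-encoded genes of oxidative phosphorylation that were tested fell as well. Rises were found in 20 of 22 hypoxia-response, 21 of 44 lysosomal, 17 of 41 autophagy machinery and 17 of 23 immediate-early genes, and each of these lists, those that fell included, had an adjusted p of 0.544 with an estimated correlation. The gene with the largest rise by the naming rule was C3, which encodes complement component 3, at 66.5 ± 9.16 FPKM in AThi (SD, n = 2) and 6.98 ± 3.18 FPKM in ATlo (SD, n = 3), a log2 fold change of 3.24 ± 0.31 (SE).

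The immediate-early list, whose genes respond to cell handling, moved with the same groups as the gene groups below, and the mitochondrially encoded share of the summed FPKM was 8.78 ± 1.79% (SD, n = 2) in AThi against 5.71 ± 0.24% (SD, n = 3) in ATlo, with an exact permutation p of 0.2. Counts of calls in single lists are to be read against the share over all genes. Of 11397 genes tested, 5884 or 51.6% passed an adjusted p of 0.05 in limma, 2529 higher and 3355 lower in AThi. Most of these changes were small, with a median absolute log2 fold change of 0.48. A fold of at least 2 was reached by 746 of them, 271 higher and 475 lower, and a fold of at least 4 by 22 higher and 133 lower. The library values of both groups did not overlap in 8013 genes, or 70.3% of those tested, where chance gives 20%. Among the 30 gene lists, 12 passed camera with the preset correlation, 6 in each direction. With the correlation estimated from the data, 0 of the 30 lists passed, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.544. That estimate rests on 3 residual degrees of freedom, so missing this test does not show that a list stayed unchanged. For G2/M, where all 35 tested genes fell, its unadjusted p was 0.140. The smallest unadjusted p was 0.0586, for autophagy machinery. Many lists share the adjusted p of 0.544 through the adjustment, so it does not rank them. By fry, which tests whether the genes of a list move one way on balance, 18 lists passed, among them 9 of the 12. The glycolysis, mitochondrially encoded and immediate-early lists missed it, with fry adjusted p-values of 0.0530, 0.0530 and 0.0590.

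**Figure D1:**
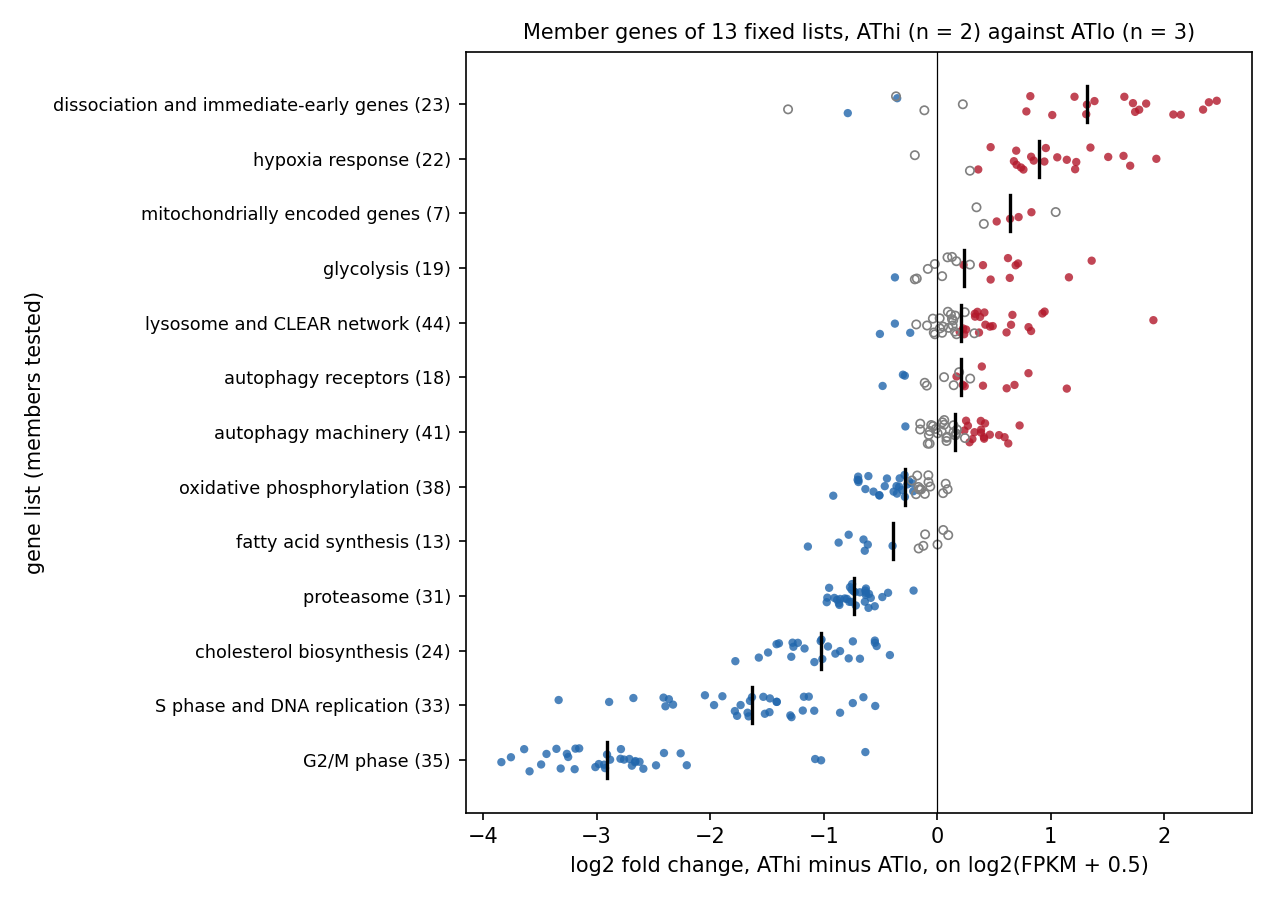
Log2 fold change (x axis, AThi minus ATlo, on log2(FPKM + 0.5)) of each tested member (points) of the 12 lists past the camera threshold and of the autophagy receptors (y axis), with the list median as a black bar. Filled points passed the limma threshold (red higher, blue lower in AThi), open points did not, and the medians run from -2.91 for G2/M to 1.32 for the immediate-early genes.

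The G2/M and S phase lists had the lowest medians of the 30 lists tested. All 35 tested genes of the G2/M list, which act in mitotic entry and chromosome segregation, fell in AThi, with a median log2 fold change of -2.91. All 33 tested genes of the S phase list, which act in DNA replication, fell as well, with a median of -1.63. The counts adjusted over the list alone were also 35 and 33. Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, changed by -3.75 ± 0.16 (SE), and Birc5, which encodes survivin, by -3.64 ± 0.13 (SE). The mitotic activator Cdc20 was at 4.54 ± 0.30 FPKM (SD, n = 2) in AThi and 48.1 ± 6.26 FPKM (SD, n = 3) in ATlo. Mki67, the gene of the proliferation antigen Ki-67, was at 1.94 ± 0.13 FPKM (SD, n = 2) against 24.7 ± 4.15 FPKM (SD, n = 3). Among replication genes, the helicase subunit Mcm5 changed by -2.68 ± 0.08 (SE), the ribonucleotide reductase subunit Rrm2 by -3.33 ± 0.13 (SE) and the licensing factor Cdc6 by -2.39 ± 0.10 (SE). The rest of the 15 largest falls taken by the naming rule were Ccnb2, Bub1, Kif20a, Pbk, Cdca3, Aurkb, Ckap2l, Pimreg and Cdkn3, with log2 fold changes between -3.59 and -3.27. Camera gave an adjusted p of 7.14e-19 for G2/M and 2.28e-16 for S phase with the preset correlation, and an adjusted p of 0.544 for each with an estimated correlation. All 35 and 33 members kept their call with any 1 library left out. Ccna2 lies on chromosome 3 (36564865 to 36572150, minus strand) and Cdc20 on chromosome 4 (118432901 to 118437352, minus strand) of GRCm38.

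Of 41 tested genes of the autophagy machinery, 17 rose, 1 fell and 23 did not pass, with a median log2 fold change of 0.16. The count adjusted over the list alone was 18. The largest rise was in Wipi1, a phosphoinositide-binding protein of the forming autophagosome, at 16.3 ± 1.32 FPKM (SD, n = 2) in AThi and 9.65 ± 0.41 FPKM (SD, n = 3) in ATlo, or 0.73 ± 0.08 (SE) on the log2 scale. Gabarapl1, which belongs to the ATG8 family together with LC3, rose by 0.63 ± 0.07 (SE), and Atg14, a subunit of the autophagy-specific PI3-kinase complex, by 0.59 ± 0.07 (SE). Map1lc3a rose by 0.54 ± 0.08 (SE). Map1lc3b, the gene of LC3B, was at 23.2 ± 0.81 FPKM (SD, n = 2) against 17.6 ± 0.69 FPKM (SD, n = 3), with an adjusted p of 0.0027. The reporter carries LC3, and no label states whether its reads were kept apart from those of Map1lc3b. The kinase genes Ulk1 and Ulk2 rose by 0.39 ± 0.08 and 0.41 ± 0.08 (SE), and Rb1cc1, Stx17, Pik3c3, Wdr45, Atg12, Atg2b, Vmp1, Gabarap, Atg13 and Pik3r4 rose by between 0.24 and 0.46. Tmem41b fell by 0.28 on the log2 scale, a call that was lost when the values were rescaled to TPM and in 4 of 5 fits with a library left out. Camera gave the list an adjusted p of 0.00145 with the preset correlation and an adjusted p of 0.544 with an estimated correlation. With each library left out in turn, 10 of the 17 rises and 0 of 1 falls kept their call every time.

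Among 18 autophagy receptors, which select cargo, 9 rose, 3 fell and 6 did not pass, and the count adjusted over the list alone was 14. The mitophagy receptor Bnip3, also a hypoxia target, rose by 1.14 ± 0.12 (SE), Calcoco1 by 0.80 ± 0.09 (SE) and Bnip3l by 0.68 ± 0.12 (SE). Sqstm1, which encodes the receptor p62, was at 180.03 ± 14.2 FPKM (SD, n = 2) in AThi and 118 ± 7.94 FPKM (SD, n = 3) in ATlo, with an adjusted p of 0.00138. Ncoa4, Nbr1, Sec62, Tex264 and Tollip rose by between 0.17 and 0.40. Phb2 changed by -0.48 ± 0.06 (SE), Bcl2l13 by -0.30 ± 0.06 (SE) and Fkbp8 by -0.29 ± 0.08 (SE). The list as a whole missed the threshold, with an adjusted p of 0.0525, and the adjusted p was 0.544 with an estimated correlation. It passed camera with the preset correlation in 5 of the alternative fits, with adjusted p-values of 0.0238 to 0.044. Among them was the fit without ATlo replicate 3 (adjusted p 0.0321). In the other alternative fits, which were the majority, the list missed the threshold, also with any other library left out. Fry gave the list an adjusted p of 0.0112, and the camera value of 0.0525 lay under the looser threshold of 0.1. In the list, 4 of the 9 rises and 2 of the 3 falls kept their call with each library left out in turn.

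Of 44 tested genes of the lysosome list, which includes targets of the CLEAR promoter element, 21 rose, 3 fell and 20 did not pass, with a median log2 fold change of 0.21, and 25 passed when adjusted over the list alone. The cathepsin F gene Ctsf rose most, from 2.72 ± 0.25 FPKM (SD, n = 3) in ATlo to 11.5 ± 0.82 FPKM (SD, n = 2) in AThi, a log2 fold change of 1.90 ± 0.09 (SE). The glycosidase genes Hexa and Gaa rose by 0.93 ± 0.12 and 0.83 ± 0.10 (SE). The membrane protein gene Lamp2 rose by 0.66 ± 0.12 (SE). Ctsa, Atp6v1b2, Psap, Sgsh, Tpp1, Ctsb, Mcoln1, Atp6ap1, Naglu, Scarb2, Glb1, Atp6v0e, Atp6v1e1 and Atp6v1a rose by between 0.20 and 0.61, and Ctsh, Gusb and Tmem55b changed by -0.50, -0.37 and -0.24. Camera gave an adjusted p of 0.000112 with the preset correlation and an adjusted p of 0.544 with an estimated correlation. With each library left out in turn, 15 of the 21 rises and 0 of the 3 falls kept their call every time.

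**Figure D2:**
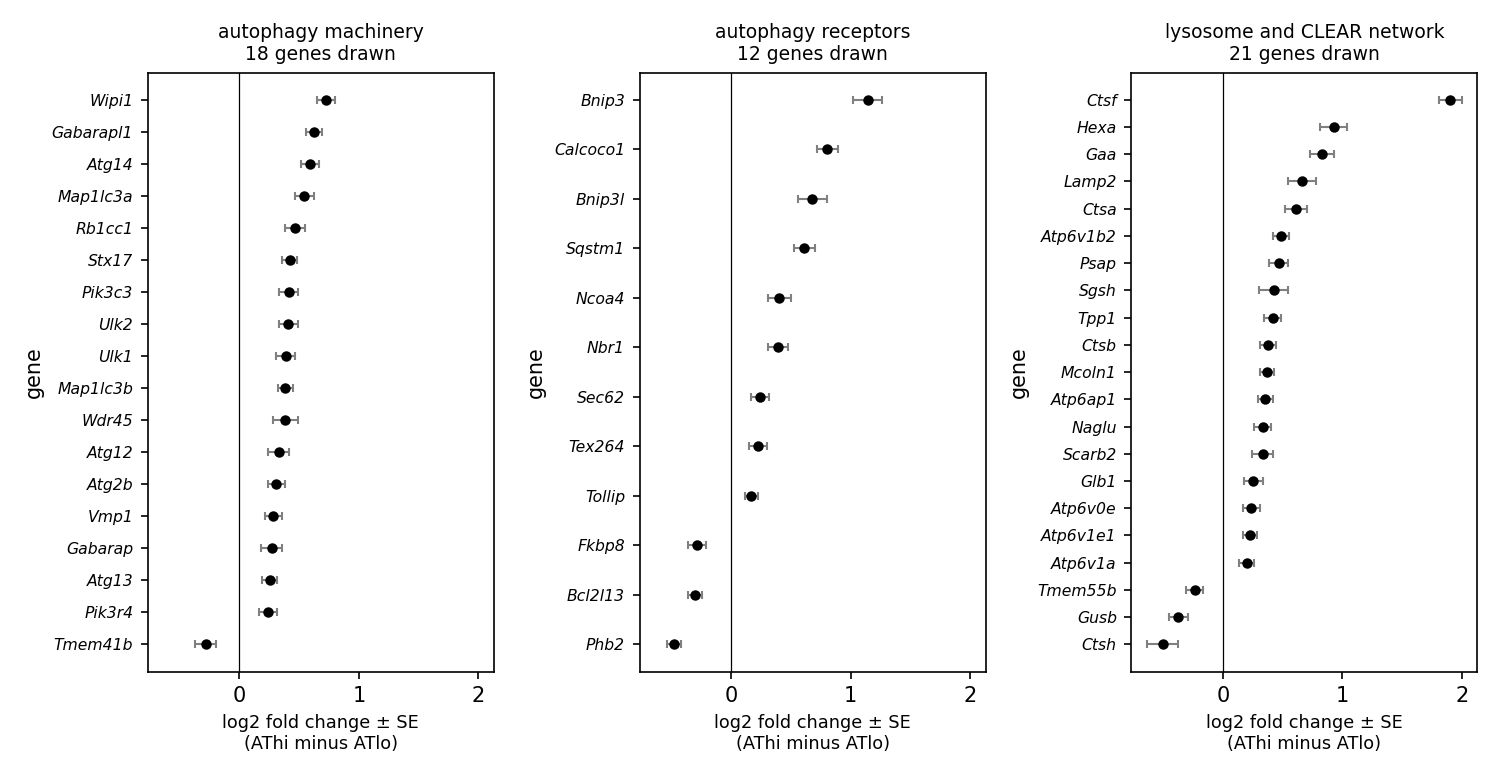
Log2 fold change with its SE (x axis, AThi minus ATlo, on log2(FPKM + 0.5)) of members past the limma threshold in the autophagy machinery, autophagy receptor and lysosome lists (y axis), with 18 of 18, 12 of 12 and 21 of 24 such genes drawn. The rises reach 0.73 for Wipi1, 1.14 for Bnip3 and 1.90 for Ctsf, and 7 genes lie below 0.

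The MiT/TFE transcription factors, which drive lysosomal genes, did not pass the test at the transcript level. Tfeb was at 3.98 ± 0.11 FPKM (SD, n = 2) in AThi and 3.57 ± 0.52 FPKM (SD, n = 3) in ATlo, with an adjusted p of 0.322, and Tfe3 had a log2 fold change of 0.03 ± 0.08 (SE) and an adjusted p of 0.771. Mitf was below the filter. Of 24 genes in the list of these factors and mTORC1 signalling, 8 rose and 4 fell, 12 in all when adjusted over the list alone. Foxo3, Sesn3, Deptor and Flcn, known as restraints on or regulators of growth signalling, rose by 0.73 ± 0.06, 0.91 ± 0.08, 0.70 ± 0.08 and 0.83 ± 0.10 (SE). Camera gave the list an adjusted p of 0.155 with the preset correlation, and fry gave it an adjusted p of 0.0165.

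Of 22 tested hypoxia-response genes, 20 rose, 0 fell and 2 did not pass, with a median log2 fold change of 0.90. Adjusted over the list alone, 21 passed. The peptide hormone gene Adm rose by 1.93 ± 0.14 (SE), the collagen prolyl hydroxylase gene P4ha2 by 1.70 ± 0.10 (SE), Ero1l by 1.64 ± 0.12 (SE) and the angiogenic factor gene Vegfa by 1.22 ± 0.15 (SE). Of 19 glycolysis genes, 9 rose, 1 fell and 9 did not pass, 11 in all when adjusted over the list alone, and both lists share 3 genes. Pfkfb3, whose product makes the activator of phosphofructokinase, rose by 1.36 ± 0.11 (SE), and Hk2 by 0.69 ± 0.10 (SE). Ldha, chosen after its values were seen, is the most abundant member of both lists and did not rise. It was at 366 and 428 FPKM in the AThi libraries and 430 to 478 FPKM in ATlo, and did not pass the threshold. Camera gave the hypoxia list an adjusted p of 5.52e-09 with the preset correlation and an adjusted p of 0.544 with an estimated correlation. For glycolysis these were an adjusted p of 0.0210 and an adjusted p of 0.546 with an estimated correlation. Without AThi replicate 2 the median of the glycolysis list fell from 0.23 to 0.12 and its adjusted p rose to 0.091.

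Of 38 nuclear-encoded genes of oxidative phosphorylation, 24 fell, 0 rose and 14 did not pass, with a median log2 fold change of -0.29 and 24 also when adjusted over the list alone. Ndufa4 changed by -0.92 ± 0.08 (SE), Ndufs8 by -0.69 ± 0.07 (SE), Cox6a1 by -0.69 ± 0.08 (SE) and the succinate dehydrogenase subunit gene Sdhb by -0.61 ± 0.07 (SE). Of the 7 tested members of the mitochondrially encoded list, 4 rose and 3 did not pass, with a median of 0.64, and 5 passed when adjusted over the list alone. These were mt-Nd5, mt-Nd4, mt-Co1 and mt-Nd2 at the threshold over all genes, with rises between 0.52 and 0.83. Camera gave adjusted p-values of 0.000108 and 0.0185, and an adjusted p of 0.544 for each list with an estimated correlation. Without AThi replicate 1, the median of the mitochondrially encoded list was 0.38 and none of these 4 genes passed, and without ATlo replicate 2 the calls of mt-Nd4, mt-Co1 and mt-Nd2 were lost. With no filter on low values none of the 4 passed, with adjusted p-values of 0.0969 to 0.582, and 14 of the 24 falls of the nuclear list kept their call with each library left out in turn.

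All 24 tested genes of the cholesterol list fell, with a median log2 fold change of -1.02, and 24 passed when adjusted over the list alone. The mevalonate kinase gene Mvk changed by -1.57 ± 0.10 (SE), Msmo1 by -1.29 ± 0.08 (SE) and Nsdhl by -1.27 ± 0.08 (SE). Of 13 genes of fatty acid synthesis, 7 fell and 6 did not pass, 7 also when adjusted over the list alone, led by the elongase gene Elovl6 at -1.14 ± 0.07 (SE) and by Acly, Scd1 and Fasn at -0.87, -0.78 and -0.65. Camera gave an adjusted p of 1.15e-09 for cholesterol and 0.0145 for fatty acids, and an adjusted p of 0.544 for each with an estimated correlation. With a minimum mean of 5 FPKM the fatty acid list missed the threshold, with an adjusted p of 0.0543.

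All 31 tested proteasome genes fell, with a median log2 fold change of -0.74 and 31 also when adjusted over the list alone. The ATPase subunit Psmc4 was at 29.9 ± 0.29 FPKM (SD, n = 2) in AThi and 59.1 ± 1.48 FPKM (SD, n = 3) in ATlo, and the regulatory subunits Psmd7 and Psmd2 changed by -0.95 ± 0.06 and -0.91 ± 0.06 (SE). Camera gave an adjusted p of 5.79e-12, and an adjusted p of 0.544 with an estimated correlation. Of 54 tested cytosolic ribosomal protein genes, 17 rose, 13 fell and 24 did not pass, 30 in all when adjusted over the list alone, and the list had an adjusted p of 0.521. Its median was 0.05 and its mean -0.03, so they differ in sign, and many of its genes have near-identical copies, so their values are uncertain.

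Immediate-early genes respond within minutes to growth signals and to cell handling. Of 23 tested genes of the dissociation and immediate-early list, 17 rose, 2 fell and 4 did not pass, with a median log2 fold change of 1.32 and 19 when adjusted over the list alone. Btg2 was at 427 ± 128 FPKM (SD, n = 2) in AThi and 79.9 ± 30.7 FPKM (SD, n = 3) in ATlo. Egr3, Egr2, Atf3 and Dusp1 rose by 2.39 ± 0.27, 2.34 ± 0.17, 2.15 ± 0.32 and 2.08 ± 0.34 (SE). The chaperone gene Hsph1 changed by -0.79 ± 0.09 (SE). Camera gave an adjusted p of 0.000349, and an adjusted p of 0.544 with an estimated correlation. With each library left out in turn, 13 of the 17 rises and both falls kept their call.

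The naming rule took further genes with large rises. Lcn2, which encodes the iron-siderophore binding protein lipocalin-2, rose by 2.85 ± 0.41 (SE) and Cybrd1, a ferric reductase gene, by 2.72 ± 0.19 (SE). Itih4, Edn2 and Agt, the genes of an inter-alpha-trypsin inhibitor heavy chain, endothelin-2 and angiotensinogen, rose by 2.49 ± 0.25, 2.13 ± 0.26 and 2.06 ± 0.23 (SE). Nepn, Arl4d and Arc rose by 2.70 ± 0.15, 2.51 ± 0.18 and 2.41 ± 0.19 (SE). The protease gene Adamts1 rose by 2.17 ± 0.52 (SE). Without AThi replicate 2 its log2 fold change was 1.33 and its adjusted p 0.0712, and the call was also lost with no filter on low values and with robust moderation, with adjusted p-values of 0.0641 and 0.0538. C3 lies on chromosome 17 (57203970 to 57228136, minus strand) and Lcn2 on chromosome 2 (32384633 to 32388252, minus strand) of GRCm38.

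**Figure D3:**
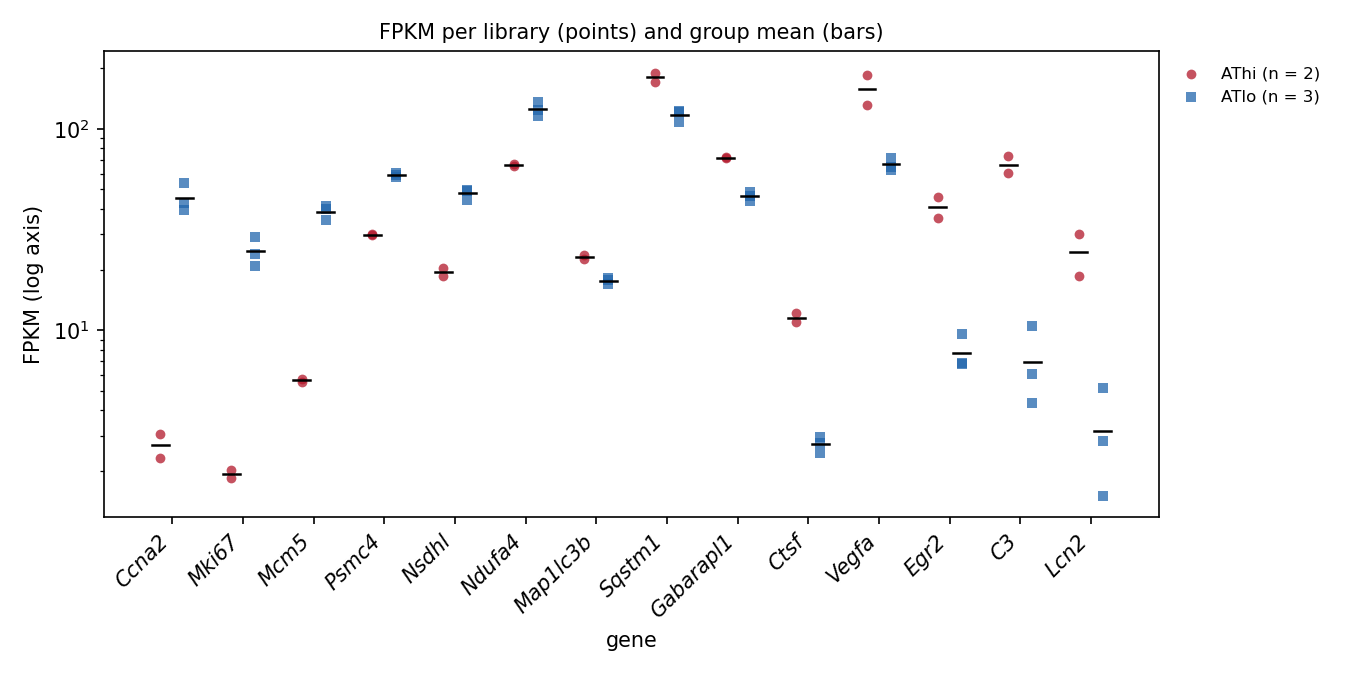
FPKM (y axis, log scale) of 14 genes (x axis) in each AThi library (circles, n = 2) and each ATlo library (squares, n = 3), with group means as bars. The groups do not overlap for any gene shown, from 2.70 against 45.4 FPKM for Ccna2 to 66.5 against 6.98 FPKM for C3.

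Most markers of other cell types were below the filter of 1 FPKM in the sorted cells. Of 20 immune markers 2 were above the filter, Cd14 at 298 ± 27.1 FPKM (SD, n = 2) in AThi and 245 ± 24.4 FPKM (SD, n = 3) in ATlo, with an adjusted p of 0.0587, and Cd68, which encodes a lysosomal membrane protein of macrophages and other cells and rose by 1.27 ± 0.19 (SE). The pan-leukocyte gene Ptprc had a mean of 0.042 FPKM. None of 15 fibroblast markers was above the filter, and Col1a1 had a mean of 0.114 FPKM. Of 12 endothelial, 16 acinar and 15 endocrine or erythroid markers 1 each was tested, Egfl7, Cela1 and Hba-a1, with log2 fold changes of -0.26, -0.21 and 1.47 and adjusted p-values of 0.101, 0.0603 and 0.0884. Hba-a1 has a near-identical copy in the genome, so its value is uncertain. Adjusted over the list alone, 2 immune markers, 1 acinar marker and 0 of the others passed. Cd14 passed under 8 alternatives (adjusted p 0.0195 to 0.0488), Hba-a1 under 4 (adjusted p 0.000318 to 0.0342), Cela1 under 3 (adjusted p 0.0292 to 0.0387) and Egfl7 under 1 (adjusted p 0.0498). Among these were the fit without ATlo replicate 1 for Cd14 and Hba-a1 and that without ATlo replicate 3 for Cela1. The share of summed FPKM in 37 mitochondrially encoded genes was 8.78 ± 1.79% (SD, n = 2) in AThi, with 10.0% and 7.51% in the single libraries, and 5.71 ± 0.24% (SD, n = 3) in ATlo, with an exact permutation p of 0.2, the smallest this design allows. Without AThi replicate 1 the difference fell from 3.07 to 1.80 percentage points. The ribosomal protein list took 2.99 ± 0.06% (SD, n = 2) and 2.71 ± 0.06% (SD, n = 3), also with an exact permutation p of 0.2, and the 20 most abundant genes took 18.1 ± 2.00% (SD, n = 2) and 17.4 ± 0.46% (SD, n = 3), with an exact permutation p of 0.8.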

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

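The voom alternative was chosen after the data were seen. No alternative reversed a named gene or list that had passed the threshold, while among those that had not passed the medians of the epithelial, mesenchymal, pancreatic, iron and unfolded protein response lists and the fold change of Tfe3 changed sign under at least 1 alternative. Of 3374 pairs of a named gene and an alternative, 109 lost the call and 16 gained it, and 30 genes lost it at least once. Of 508 pairs of a list and an alternative fit, all by camera with the preset correlation, 2 lost the call (fatty acid synthesis with a mean of at least 5 FPKM, glycolysis without AThi replicate 2) and 8 gained it. These pairs leave out camera with an estimated correlation, where all 12 lists lost the call. They also leave out fry, where 9 of the 12 kept it and 18 lists passed, and the threshold of 0.1, where 14 lists passed. The 5884 genes past the threshold ranged from 4309 to 5718 with 1 library left out, of which 4161 and 5378 were shared with the full set (1715 to 2467 higher, 2594 to 3251 lower, 11 to 13 lists), and where 1 AThi library was left it was assumed to vary like ATlo. Requiring a fold of 2 gave 746 genes, 271 higher and 475 lower, because small changes are removed. A minimum mean of 5 FPKM gave 1683 genes higher in AThi, with fewer genes tested. Camera with an estimated correlation gave 0 lists. Voom on estimated reads gave 6007 genes. Under other scalings the share of calls that were higher moved from 43.0% to at most 51.5% (quantile normalization), and no scaling moved the median of all genes by over 0.1. Same-numbered libraries share the start of a sample code, and no label says what the code marks. With the replicate number as a block, 5909 genes passed (2579 higher, 3330 lower), and 13 lists. Of the named genes, Atp6v0e, Atp6v1a, Atp6v1e1, Pik3r4, Tex264, Tmem41b, Tmem55b and Tollip then lost the call, and Cd14, Cela1 and Hba-a1 gained it. Deviations from the group means correlated at 0.20 and 0.30 across genes between same-numbered libraries. With 2 AThi libraries their deviations are equal and opposite, so these values are not independent and give at most a weak hint of pairing. Depth limits genes near 0.1 FPKM, below the filter of 1.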

Other observations

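Further gene groups of tumour cell state held both rises and falls. Over all tested genes 51.6% passed, in both directions, so a mix near that share does not set a list apart. In the amino acid stress list, 8 of 26 tested genes rose and 12 fell. The serine synthesis genes Phgdh and Psat1 had log2 fold changes of -1.57 ± 0.08 and -1.50 ± 0.09 (SE), and Shmt2 and Asns of -1.06 ± 0.06 and -0.92 ± 0.07 (SE). In the NRF2 list, 4 of 22 rose and 13 fell, with Nqo1 at -1.27 ± 0.08, Gsr at -1.06 ± 0.09, Taldo1 at -0.95 ± 0.06 and Gclc at 0.81 ± 0.07 (SE). The iron list had 4 rises and 6 falls among 17, including the iron exporter gene Slc40a1 at 0.95 ± 0.10, Hmox1 at 1.24 ± 0.16 and Slc7a11 at -1.57 ± 0.18 (SE). The unfolded protein response list had 4 rises and 8 falls among 24. Adjusted over the list alone, 20, 18, 12 and 12 genes of these lists passed. None of these lists passed camera, with adjusted p-values of 0.364, 0.177, 0.895 and 0.667, although NRF2 did with no filter on low values, with an adjusted p of 0.0237. By fry the amino acid stress and NRF2 lists passed, with adjusted p-values of 0.0400 and 0.00959. The iron and unfolded protein response lists missed it, with fry adjusted p-values of 0.0806 and 0.0700. With all settings as in the report, the adjusted p of NRF2 was 0.544 with an estimated correlation.

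Genes of cell identity were mixed as well. Tff1, a secreted trefoil peptide gene, was at 2521 ± 532 FPKM (SD, n = 2) in AThi and 7085 ± 327 FPKM (SD, n = 3) in ATlo, while Sox9 changed by 1.01 ± 0.12 (SE), Anxa10 by -1.10 ± 0.07 (SE) and Foxa1 by -0.66 ± 0.07 (SE). The call of Tff1 was lost without the filter on low values. Of 18 genes of that list 7 rose and 5 fell. The epithelial list had 4 rises and 3 falls among 17, with the stem cell-associated surface gene Prom1 at 1.43 ± 0.10 (SE), and the mesenchymal list 5 and 3 among 12, with Vim at -0.61 ± 0.07 (SE). Rises and falls were 4 and 3 of 12 for stem cell-associated, 1 and 4 of 9 for basal-like, 8 and 4 of 15 for growth factor, 5 and 6 of 20 for MAPK, and 5 and 5 of 20 for p53 genes. They were 6 and 2 of 16 for class I presentation, 7 and 2 of 14 for interferon, and 6 and 4 of 21 for NF-kB genes. In the order of this paragraph the counts adjusted over the list alone were 12, 4, 8, 7, 5, 14, 11, 10, 10, 9 and 11, and the adjusted p-values were 0.706, 0.896, 0.850, 0.396, 0.396, 0.364, 0.825, 0.508, 0.177, 0.0635 and 0.402. The interferon list passed without AThi replicate 1 and with no filter on low values, with adjusted p-values of 0.0392 and 0.0473. Its adjusted p was 0.544 with an estimated correlation and the settings of the report, and its camera value of 0.0635 lay under the looser threshold of 0.1. By fry the interferon, stem cell-associated and basal-like lists passed, with adjusted p-values of 0.0188, 0.0315 and 0.0426. The growth factor and class I lists passed fry as well, with adjusted p-values of 0.0301 and 0.0426, and the others of this paragraph did not. Median and mean differed in sign in the epithelial, mesenchymal, pancreatic and MAPK lists, for all of which the direction of camera was up. Chosen after values were seen, Lgals1 and S100a6 were among the abundant genes that changed by a fold of at least 2, at -1.31 ± 0.08 and -1.09 ± 0.13 (SE), as were Bsg and Dmbt1, at 1.24 ± 0.10 and 1.53 ± 0.21 (SE).

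The tests of sequencing depth, shared sample code and single library below were chosen only after the result was seen, and the rule that a value must clear its bound with its whole spread was settled after the values were known. The fall of the 35 G2/M genes was set against scaling, depth and sequence composition. Under TPM, median-ratio, quantile and top-gene-removed scaling the list median nearest 0 was -2.86. The 2 AThi libraries are the shallowest and the deepest of the 5, and the one nearer to ATlo differed from the ATlo mean by a median of -2.84, with -3.23 to -2.59 over the 6 pairs of an AThi and an ATlo library. After trends with GC content and transcript length, known for 98.5% of tested genes, were removed, the median was -2.89. The median log2 fold change of all genes was -0.028 in the main fit and 0.0044 to 0.031 under these scalings. Removing both trends moved genes by a median of 0.055. The scaling and composition corrections were thus small and could not have removed a fall of this size. Their small size argues against both as the whole cause, and the depth values argue against depth as the whole cause. Whether fewer AThi cells were dividing, and whether the gate itself selected cells by cell cycle stage or size, was not tested.

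For the immediate-early genes, handling and a shared day were weighed. Of the 18 members that are not heat-shock genes, 16 rose. Between AThi and ATlo libraries whose sample codes begin alike, the median difference was 1.23 for one code and 1.55 for the other, which argues against a day marked by the code as the whole cause. The 5 heat-shock members had a median of -0.36, with 1 rise, 2 falls and a range of -0.77 to 1.13 over library pairs, so a general stress response to handling cannot be told apart from other causes, since these members move both ways and Hspa1a and Hspa1b vary between libraries. A longer time between dissociation and lysis for one of the gates could give the same rise, and the labels used here do not give such times.

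Of the 7 tested members of the mitochondrially encoded list 4 rose, none of which kept its call with every library left out in turn. The mitochondrially encoded mt-Rnr1, not on the list and chosen after its values were seen, rose by 1.25 ± 0.24 (SE). It was at 972 and 1026 FPKM in AThi replicates 1 and 2, and at 338, 360 and 601 FPKM in ATlo replicates 1 to 3. Of 38 nuclear oxidative phosphorylation genes 24 fell. With the mitochondrial and 20 most abundant genes left out and the libraries rescaled, the median of the nuclear list moved from -0.29 to -0.23. It lay between -0.33 and -0.17 over library pairs, with quartiles of -0.44 and -0.10 over genes and 22 of 38 genes counted as lower. Leaving these genes out moved the median of all genes from -0.028 to 0.023, so the correction was small and could not have removed the fall. Its small size argues against displacement by abundant transcripts as the whole cause of that fall. AThi replicate 2 alone lay above the ATlo mean by a median of 0.38 over the 7 mitochondrially encoded genes, with quartiles of 0.23 and 0.53, and above every ATlo library in 6 of the 7. This goes against a rise in replicate 1 alone, but the quartiles are those of genes within 1 library, which has no replicate of its own, so whether the rise rests on AThi replicate 1 cannot be told apart from a rise in both libraries with 2 libraries.

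Of the 13 mitochondrially encoded genes listed, 5 (mt-Nd3, mt-Nd4l, mt-Co3, mt-Atp6 and mt-Atp8) were listed at 0 in all 5 libraries, and mt-Co2 at 0.05 FPKM in AThi replicate 1 and 0 in the others, although mt-Co1 was between 4219 and 9235 FPKM. Of 55 cytosolic ribosomal protein genes, 17 had a mean under 10 FPKM and 18 a mean of at least 100 FPKM, and Gapdh, chosen after its values were seen, had a mean of 8.39 FPKM.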
